A study of Mus musculus with 12 samples.

How the data were processed

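RNA abundance was measured on 12 Affymetrix microarrays from mice and mouse cells, 3 arrays in each of 4 groups. Per the labels, the groups were leukemia from the spleen of a NOTCH1 leukemia model, GFP-positive colonies described as partially reprogrammed, GFP-negative colonies described as reprogrammed, and established induced pluripotent stem (iPS) cells. The labels give a mouse genotype that carries an inducible cassette of the reprogramming factors Pou5f1, Sox2, Klf4 and Myc, but do not say what GFP marks. Total RNA was extracted with Trizol and labelled by a standard Affymetrix protocol, per the labels' protocols. The replicate numbers come from the sample titles, which call the arrays of a group biological replicates without saying whether these were separate animals or cultures, so p-values measure the spread between these arrays. The leukemia titles all carry the same leukemia number.

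The authors deposited log2 values, 1 per probe set and array, made with RMA (background correction, quantile normalization and median polish of probes into probe sets), per the submitters' processing notes. The RMA software and its version, and any filter on probe sets, are not given in the sources used here. Quantile normalization makes the distributions of the arrays nearly equal, so a change of most genes in 1 direction would be removed. Array medians lay between 5.76 and 5.82 and upper quartiles between 7.41 and 7.50 on the log2 scale. No background or detection values were used here, so signal over background was not measured, and the number of arrays limits the precision.

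The table held 41345 probe sets with 0 missing values and 0 pairs of identical arrays. The platform annotation used here paired 23521 probe sets with 1 gene symbol and 1814 with several, and 16010 probe sets had no gene annotation here. Probe sets with several symbols or none were left out of gene tests. For the 1082 genes with more than 1 probe set, the probe set with the highest mean over all arrays was used, which left 22180 genes. Entrez identifiers of 21994 of these genes were in the RefSeq table used here (assembly GRCm38.p6, used for names only), where 0 symbols differed, and 186 were not. No called probe set of a named gene went in the opposite direction to the one used. The probe sets of the genes reported in every comparison were 17337155 for Pou5f1, 17396878 for Sox2, 17425401 for Klf4, 17311846 for Myc, 17462694 for Nanog, 17383052 for Notch1, 17526464 for Cd3e, 17227536 for Ptprc, 17340272 for Epcam, 17255260 for Col1a1. The probe sets of Pou5f1, Sox2, Klf4 and Myc may read transcripts of the cassette as well as of the endogenous genes, which was not examined here. Whether the Notch1 probe set reads any NOTCH1 transcript particular to the leukemia model was not examined either.

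A linear model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation, and 6 comparisons were taken from it. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 22180 genes. Differences are log2 with the standard error of the fit, and levels are means ± SD of 3 arrays.

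The comparisons, the tests, the alternatives apart from those named last, 20 gene lists and the rule for named genes were fixed before the data were examined. The lists covered pluripotency genes outside the cassette, the reprogramming factors, T lineage genes, Notch pathway and Notch1 target genes, pan-haematopoietic, epithelial, fibroblast and mesenchymal, macrophage and granulocyte, B cell, erythroid, imprinted, early germ-layer, germline, cell division, cell cycle inhibitor and p53, glycolysis, antigen presentation, sex-chromosome and housekeeping genes, and regulators of DNA methylation and Polycomb. For each list the number of called members was counted, over all genes and adjusted over the list alone. Its genes were set against all other genes with camera at a preset correlation of 0.01, adjusted over the 20 lists of a comparison, and again with the correlation estimated from the data.

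The genes named were, in the comparisons of the 3 successive steps and of iPS cells with leukemia, the 5 largest increases and the 5 largest decreases among called genes whose 3 arrays of one group all lay above those of the other, without clone, predicted-model and locus names, and the 2 called members of each list with the largest differences. Pou5f1, Sox2, Klf4, Myc, Nanog, Notch1, Cd3e, Ptprc, Epcam and Col1a1 were reported in all 6 comparisons. Genes outside this rule are said to be chosen after their values were seen. A position index placed each array on the axis from the leukemia mean (0) to the iPS mean (1) over the genes called between these groups by at least 2-fold, and the colony groups were compared with a two-sided exact permutation test.

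The steps were tested on simulated data of 22180 genes with 200 changed genes, each group keeping its measured spread. Of genes changed by a log2 of 2, the fit recovered 97% for GFP-positive colonies against leukemia, 98% for GFP-negative against GFP-positive colonies, 97% for iPS cells against GFP-negative colonies and 94% for iPS cells against leukemia. For a log2 of 1 these shares were 77%, 79%, 80% and 78%, in the same order. False calls made up 15.1%, 54.0%, 28.6% and 1.15% of the calls. With a spread allowed to differ between groups they made up 25.3%, 27.7%, 32.9% and 10.6%. With only the 6 arrays of the groups compared, false calls made up 16.3%, 7.26%, 21.3% and 8.26%. That fit recovered 71%, 25%, 65% and 100% of the genes changed by a log2 of 1, and 99%, 90%, 90% and 100% of those changed by 2. With equal spread in all groups they made up 7.82%, 5.68%, 3.85% and 7.22% in the 4-group fit. The comparisons of GFP-negative colonies with leukemia and of iPS cells with GFP-positive colonies were not simulated. A share of false calls depends on how many genes truly change, so these shares are not error rates of the real calls. Between the colony groups the simulated 4-group fit made 208 false calls, whereas the real fit called 0 genes, so the simulation did not reproduce that comparison.

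The alternatives were the replicate number as a block, only the 6 arrays of the groups compared, an intensity trend with a robust prior, array weights, the mean of all probe sets of a gene, all probe sets tested, only genes above the 40th percentile, cyclic loess, centring on the housekeeping genes, a 2-fold minimum, and leaving out each array in turn. Chosen after seeing the data were a block for the Y-linked genes, a spread that may differ between groups, and leaving out both GFP-positive replicate 3 and GFP-negative replicate 1.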

Results

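Expression profiles were available for spleen leukemia of the NOTCH1 mouse model, for GFP-positive and GFP-negative reprogramming colonies, and for established iPS cells, with 3 arrays per group. The series names the mouse model, and its groups run from the leukemia through partially reprogrammed and reprogrammed colonies to iPS cells. Values are log2 probe-set levels, differences are log2 ± standard error from limma, and n = 3 arrays per group throughout. The sample titles call the arrays of a group biological replicates, without saying whether these were separate animals or cultures.

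The arrays fell into a tight leukemia group, a tight iPS group and widely spread colonies. T lineage genes averaged 9.83 ± 0.02 in leukemia, 5.85 ± 0.27 in GFP-positive colonies, 5.61 ± 0.18 in GFP-negative colonies and 5.51 ± 0.14 in iPS cells. Pluripotency genes averaged 6.03 ± 0.09, 8.34 ± 1.20, 8.58 ± 1.72 and 9.74 ± 0.02 in the same order, and epithelial genes 5.89 ± 0.03, 9.63 ± 0.32, 9.03 ± 1.08 and 8.20 ± 0.03. Correlations across genes between arrays of a group were 0.994 in leukemia and 0.995 in iPS cells, against 0.937 to 0.975 in GFP-positive and 0.887 to 0.970 in GFP-negative colonies. The median SD over genes was 0.105, 0.217, 0.245 and 0.0998 in leukemia, GFP-positive colonies, GFP-negative colonies and iPS cells. The pluripotency list averaged 6.61 on GFP-negative replicate 1, against 9.35 and 9.78 on replicates 2 and 3, and 7.15 on GFP-positive replicate 3, against 8.32 and 9.55 on replicates 1 and 2. GFP-negative replicate 1 stood apart from the others of its group on this list. The GFP-positive arrays were spaced about evenly on it, with replicate 2 highest. By correlation across genes GFP-positive replicate 3 stood apart, at 0.955 and 0.937 with replicates 1 and 2, which correlated at 0.975.

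**Figure D1:**
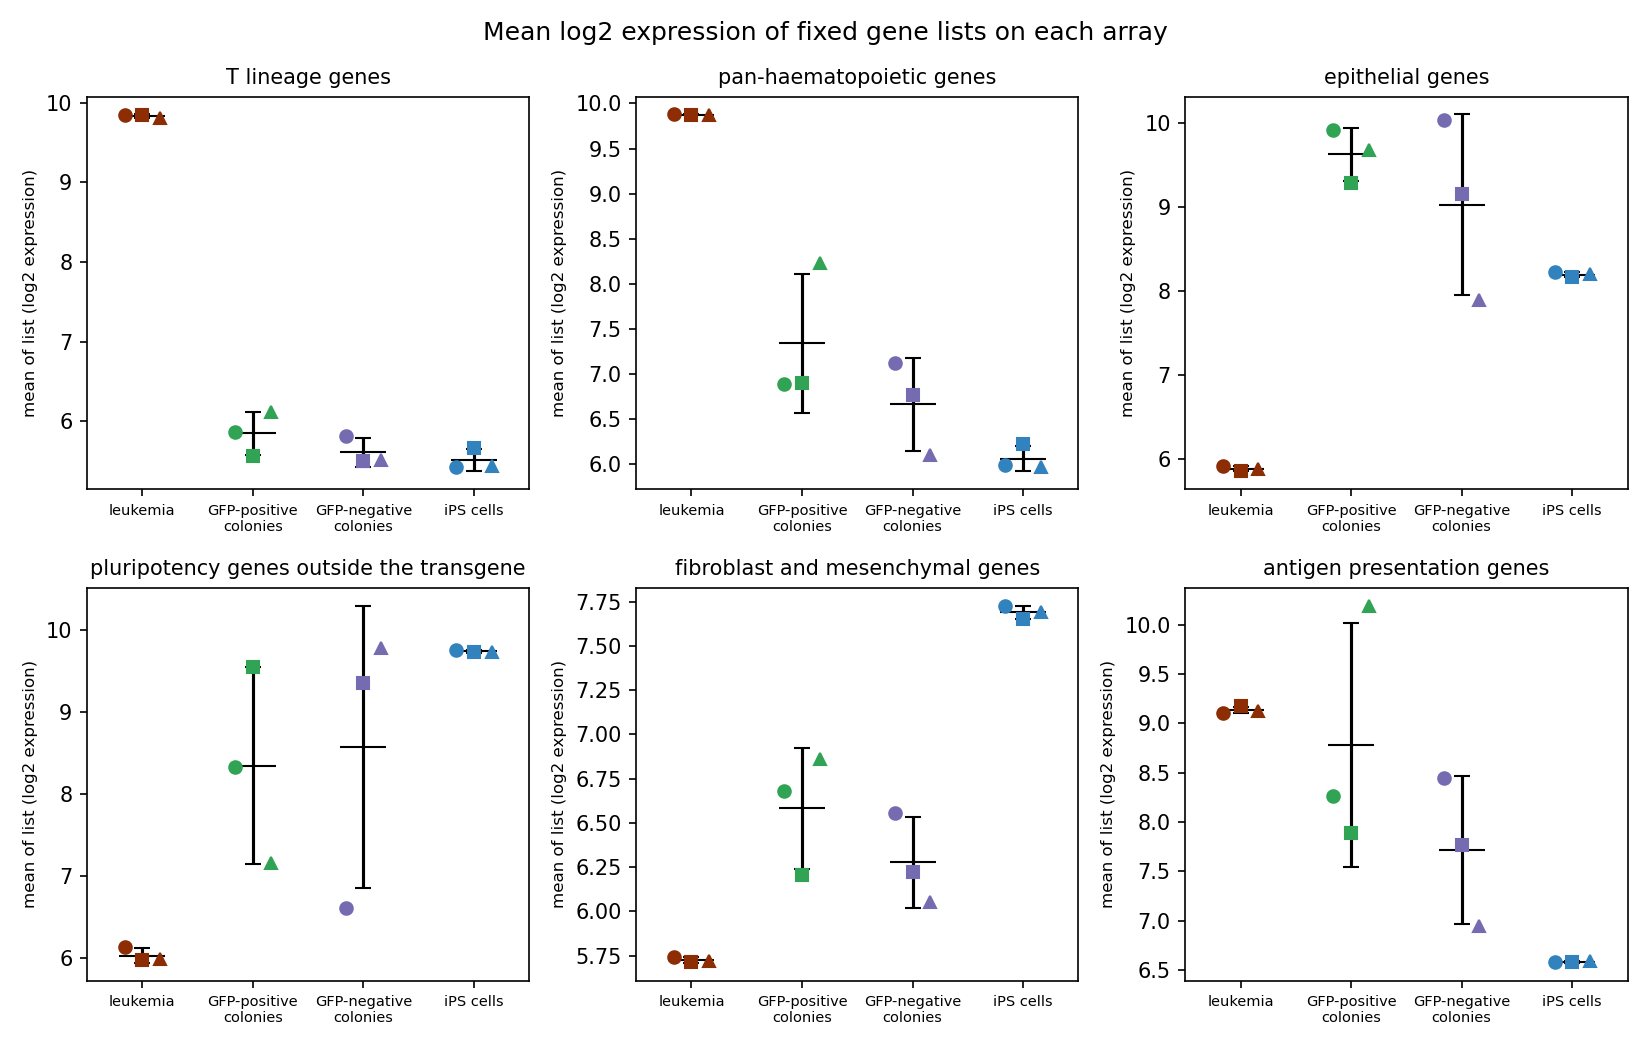
Mean log2 level of gene lists on each array, by group, with 1 point per array. The T lineage points of the leukemia arrays lie near 9.8 and those of all other arrays between 5.42 and 6.11, and the pluripotency points of the colonies spread from 6.61 to 9.78.

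GFP-positive colonies had lower T cell and wider blood expression than the leukemia and higher expression of epithelial genes. All 27 measured T lineage genes fell (27 adjusted over the list alone), with a median difference of -3.87. Cd3g, a chain of the CD3 complex, differed by -6.41 ± 0.52 (adjusted p = 1.1e-05, limma) and Cd8b1, the CD8 beta chain, by -5.90 ± 0.34. Of 20 epithelial genes 18 rose (19 adjusted over the list alone), with a median of 3.60, among them Cdh1, which encodes E-cadherin, by 6.46 ± 0.30 and Krt18 by 5.82 ± 0.80. The cell adhesion gene Epcam rose from 4.97 ± 0.10 to 9.43 ± 0.19 (adjusted p = 9.32e-08).

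The 5 largest increases were those of the keratin genes Krt6a (269-fold, 8.07 ± 1.54, adjusted p = 0.00365), Krt14 (7.07 ± 1.32) and Krt17 (6.78 ± 0.66), of Nid1, a basement membrane component (6.85 ± 0.58), and of Fgfbp1, a carrier of fibroblast growth factors (6.74 ± 0.51). The 5 largest decreases were those of the trypsinogen gene Prss2 (-6.56 ± 0.17, adjusted p = 5.28e-09), Cd3g, the neutrophil granule gene Ngp (-6.30 ± 0.23), the lymphocyte receptor gene Slamf6 (-6.29 ± 0.17) and the T cell receptor segment Trav9d-3 (-6.18 ± 0.28). Probes of gene families such as keratins, receptor segments and trypsinogens can cross-hybridise to related genes.

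Blood genes outside the T lineage were lower as well. The leukemia came from the spleen per the labels, and which cell types its arrays held was not measured here. Of 25 pan-haematopoietic genes 23 fell and 2 were not called (24 fell adjusted over the list alone), including Coro1a, a leukocyte actin regulator (-4.20), Ikzf1, the Ikaros transcription factor (-3.86), and Ptprc, which encodes CD45 (-2.41 ± 0.73, adjusted p = 0.038). Of 20 macrophage and granulocyte genes 6 fell and 1 rose (6 and 1 adjusted over the list alone), with the granule genes Ngp and Camp (-5.83) falling furthest. The list averaged 6.13, 6.03 and 8.18 on GFP-positive replicates 1, 2 and 3 and 8.13 to 8.20 on the leukemia arrays, and 12 of the 20 fell without GFP-positive replicate 3. Of 10 B cell genes 5 fell (5 adjusted over the list alone), Ighm at -3.81 and Cd22 at -0.98. Of 9 erythroid genes 7 fell and 1 rose (7 and 1 adjusted over the list alone). Both examples are carbonic anhydrases, Car1 at -2.94 and Car2 at 2.75. Antigen presentation genes had 0 of 13 called (0 adjusted over the list alone) and a median of -0.49 (limma, camera adjusted p = 0.665, and adjusted p = 0.883 with an estimated correlation). Their list averaged 8.26, 7.89 and 10.19 on the GFP-positive arrays and 9.11 to 9.17 on the leukemia arrays, and the median was -0.97 without GFP-positive replicate 3, where 3 genes fell, -0.08 without replicate 1 and 0.13 without replicate 2.

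Several Notch genes were lower in the colonies. Of 16 Notch pathway and target genes 7 fell and 1 rose (8 and 2 adjusted over the list alone), with a median of -0.31 (camera adjusted p = 0.0199, and adjusted p = 0.127 with an estimated correlation). Notch1 itself went from 11.32 ± 0.01 to 8.95 ± 0.15 (adjusted p = 6.7e-08), and Ptcra, the pre-T cell receptor alpha chain and a Notch target, differed by -2.58 ± 0.10. Of the factors of the cassette, Pou5f1 rose by 0.68 ± 0.17 and Myc, itself a Notch1 target in T cell leukemia, differed by -1.32 ± 0.29 (adjusted p = 0.00799). Sox2 (3.79 ± 1.32, adjusted p = 0.0664) and Klf4 (0.57 ± 0.31, adjusted p = 0.231) were not called. For these 4 genes 2 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.312).

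Of 28 pluripotency genes outside the cassette 8 rose and 20 were not called (11 rose adjusted over the list alone), with a median of 2.27. Tdgf1, the Nodal co-receptor, rose by 6.34 ± 0.53, the transcription factor Tfcp2l1 by 5.21 ± 0.28, and Nanog by 5.10 ± 1.53 (adjusted p = 0.0371). Without GFP-positive replicate 3 and GFP-negative replicate 1, left out after their values were seen, 24 of the 28 rose. Without GFP-positive replicate 3 alone 15 rose, and 5 without any other array of the comparison. The median was 1.41 without GFP-positive replicate 2. Of 23 fibroblast and mesenchymal genes 6 rose (8 adjusted over the list alone), fibronectin (Fn1) by 5.66 and fibulin-2 (Fbln2) by 2.34, whereas Col1a1 was not called (0.70 ± 0.32, adjusted p = 0.154). Of 19 imprinted genes 5 rose (6 adjusted over the list alone), among them Mest (2.32) and Grb10 (2.18). Among 20 DNA methylation and Polycomb regulators 4 rose and 4 fell (5 and 4 adjusted over the list alone), the Polycomb gene Phc1 rising by 2.39 and the dioxygenase gene Tet2 3.99-fold.

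The cell division list had 2 members that fell, Mki67 (-1.38) and Pcna (-0.83), and 13 not called (7 fell adjusted over the list alone, median -0.73). The cell cycle inhibitor and p53 list had 3 that rose and 2 that fell (5 and 2 adjusted over the list alone), with the inhibitor gene Cdkn1a up by 3.67 ± 0.35 and the stress gene Sesn2 by 1.87. Of 14 glycolysis genes 6 rose (6 rose and 1 fell adjusted over the list alone), the glucose transporter genes Slc2a1 by 2.30 and Slc2a3 by 1.61. Of 23 early germ-layer genes 2 rose (2 adjusted over the list alone), Otx2 by 2.80 and Dab2 by 1.84. Of 15 germline genes 0 were called (0 adjusted over the list alone, limma) at a median of 0.38. Of 4 sex-chromosome genes 1 fell (1 adjusted over the list alone), namely Xist, the RNA that coats the inactive X chromosome (-2.84 ± 0.92, adjusted p = 0.0493). This fall rests mainly on GFP-positive replicates 1 and 2, since Xist on replicate 3 lay just below the leukemia arrays. Among 15 housekeeping genes 5 rose and 1 fell (5 and 1 adjusted over the list alone), Chmp2a rising by 0.80 and Rab7 by 0.79.

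Against all other genes, camera with the preset correlation placed 14 of these lists above or below the rest, and 2 of these calls were kept with an estimated correlation. Those were the T lineage list (camera adjusted p = 8.87e-34, and adjusted p = 0.0126 with an estimated correlation) and the erythroid list (camera adjusted p = 4.27e-05, and adjusted p = 0.0428 with an estimated correlation). The epithelial list had a camera adjusted p = 5.14e-17, and adjusted p = 0.127 with an estimated correlation. For pluripotency genes it was camera adjusted p = 2.25e-07, and adjusted p = 0.366 with an estimated correlation. For the pan-haematopoietic list it was camera adjusted p = 5.23e-14, and adjusted p = 0.157 with an estimated correlation. Over the 12 lists whose call was lost, the adjusted p with an estimated correlation ran from 0.0901 for B cell genes to 0.535 for cell division genes.

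Single arrays moved other list results by over 1.5 times. The Notch median was -0.12 without GFP-positive replicate 2 and -0.68 without replicate 3, the cell division median -0.46 without replicate 3, and the germline median 0.22 without replicate 2 and 0.63 without replicate 3. Of the fibroblast genes 10 rose without GFP-positive replicate 2. Imprinted genes that rose numbered 8 without GFP-positive replicate 3, 2 without leukemia replicate 2 and 3 without any other array. Glycolysis genes that rose numbered 3 without GFP-positive replicate 1 or any leukemia array, and housekeeping genes 3 without GFP-positive replicate 3 and 2 without GFP-positive replicate 1 or any leukemia array.

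In all, 2129 genes were higher and 2719 lower in GFP-positive colonies than in leukemia, of 22180 tested (limma). At least 2-fold differences were found for 1394 and 991 of them. The share of higher genes among the calls was 43.9%, and 57.1% after cyclic loess. Of the 47 calls of named genes 38 were kept whichever array was left out. The other 9 were lost without at least 1 array: Pou5f1 without leukemia replicate 2 (adjusted p = 0.0656), and Mest, Otx2, Slc2a3, Xist, Chmp2a, Nanog, Cd3e and Ptprc without any 1 of 5 of the 6 arrays, with highest adjusted p values from 0.0659 for Cd3e to 0.154 for Xist.

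**Figure D2:**
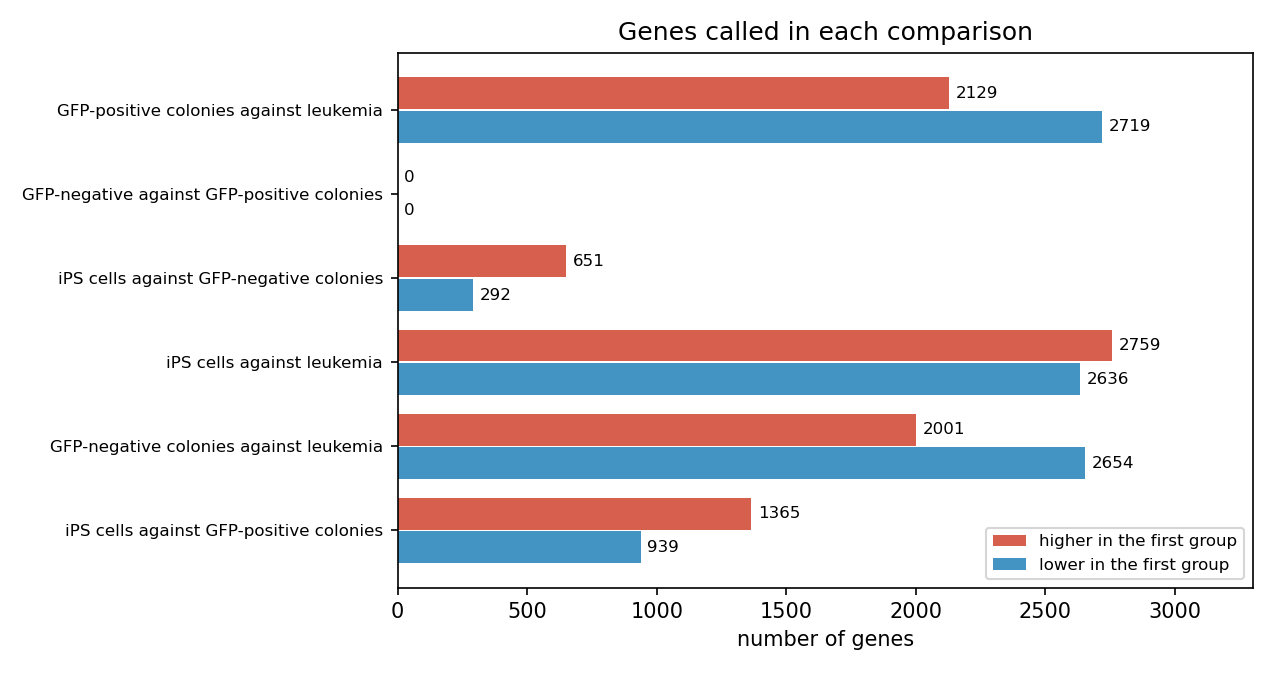
Number of genes called higher and lower in each of the 6 comparisons (limma, adjusted p under 0.05, 22180 genes). The comparison of the colony groups has 0 calls, and iPS cells against GFP-negative colonies 651 higher and 292 lower.

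No gene distinguished GFP-negative from GFP-positive colonies over the spread between arrays. Limma called 0 genes higher and 0 lower, 1413 genes had an unadjusted p under 0.05 where 1109 would by chance, and the smallest adjusted p was 0.141. Ptprc measured 6.69 ± 1.57 in GFP-negative and 9.33 ± 1.25 in GFP-positive colonies (-2.64 ± 0.73, adjusted p = 0.708), and Cd3e 7.33 ± 2.16 and 8.78 ± 0.70. Differences were -0.95 ± 0.31 for Klf4, -0.29 ± 0.09 for Notch1, -0.40 ± 0.32 for Col1a1, -0.32 ± 0.29 for Myc and -0.40 ± 1.53 for Nanog. For Pou5f1 (0.09 ± 0.17), Sox2 (0.05 ± 1.32) and Epcam (0.01 ± 0.19) they were smaller than their standard errors.

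Among the lists, camera with the preset correlation placed pan-haematopoietic genes (median -0.60, camera adjusted p = 1.22e-06, and adjusted p = 0.639 with an estimated correlation) and antigen presentation genes (median -1.01, camera adjusted p = 1.22e-06, and adjusted p = 0.639 with an estimated correlation) lower in GFP-negative colonies. It also placed epithelial genes (median -0.53, camera adjusted p = 3.47e-04, and adjusted p = 0.651 with an estimated correlation) and fibroblast genes (median -0.27, camera adjusted p = 5.58e-04, and adjusted p = 0.639 with an estimated correlation) lower. The same held for Notch genes (median -0.14, camera adjusted p = 0.0127, and adjusted p = 0.319 with an estimated correlation), T lineage genes (median -0.13, camera adjusted p = 0.0176, and adjusted p = 0.651 with an estimated correlation) and macrophage and granulocyte genes (median -0.47, camera adjusted p = 0.0176, and adjusted p = 0.703 with an estimated correlation). On GFP-positive replicate 3 the pan-haematopoietic, antigen presentation and macrophage lists averaged 8.23, 10.19 and 8.18, against at most 7.12, 8.44 and 6.94 on the other colony arrays. Each of these 7 medians moved by over 1.5 times without at least 1 array. Without GFP-positive replicate 3 it was -0.05 for pan-haematopoietic, -0.58 for antigen presentation, -0.17 for fibroblast, -0.05 for T lineage and 0.34 for macrophage genes, the last higher in GFP-negative colonies. Without GFP-negative replicate 3 it was -0.06 for epithelial, -0.32 for pan-haematopoietic, -0.66 for antigen presentation, -0.04 for T lineage and -0.16 for macrophage genes, and without GFP-negative replicate 1 -1.03 for epithelial, -1.55 for antigen presentation, -0.43 for fibroblast, -0.25 for T lineage and -0.26 for Notch genes. Without GFP-positive replicate 2 it was -0.27 for Notch, -0.24 for T lineage, -0.46 for fibroblast and -0.96 for macrophage genes. Without GFP-positive replicate 1 it was -0.92 for pan-haematopoietic and -0.89 for macrophage genes, and -0.76 for the latter without GFP-negative replicate 2. No list was called with an estimated correlation, and 0 members of any list were called over all genes. Adjusted over the list alone, the transcription factor gene Bcl11b of T cells (-1.09 ± 0.25), Klf4 and the Notch target Nrarp (-1.26 ± 0.27) were lower, and the Notch effector gene Rbpj (0.74 ± 0.21) higher, genes named after their values were seen except Klf4. Pluripotency genes had a median of 0.19 (camera adjusted p = 0.6, and adjusted p = 0.944 with an estimated correlation). Their median was 1.08 without GFP-negative replicate 1 and 0.73 without GFP-positive replicate 2, and turned to -0.07 without GFP-negative replicate 2, -0.34 without GFP-negative replicate 3 and -0.23 without GFP-positive replicate 3.

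Single arrays weighed heavily on this comparison. Krt6a, which encodes a keratin of stratified epithelium, measured 11.79, 11.63 and 12.92 on the GFP-positive arrays and 11.91, 5.22 and 4.09 on GFP-negative replicates 1, 2 and 3. Nanog measured 9.56, 11.93 and 7.97 on the GFP-positive arrays and 5.07, 11.35 and 11.85 on the GFP-negative arrays. Without GFP-negative replicate 1, limma called 251 genes higher and 768 lower. Without GFP-positive replicate 2 it called 2 lower, Lce3a (-2.05 ± 0.21) and Plbd1 (-1.56 ± 0.16), and 1 without GFP-positive replicate 3, Cubn (-2.91 ± 0.28), genes that the rule did not choose and that are named after their values were seen. With array weights 405 were higher and 910 lower, and with both arrays that stood apart left out, 273 and 776. The fit of these 6 arrays alone called 0 genes, with 393 at an unadjusted p under 0.05 where 1109 would be by chance. With a spread allowed to differ between groups this number was 552, also below 1109, so the excess of the 4-group fit was not kept. In simulated data with the measured spread and 200 changed genes, 54.0% of the calls of the 4-group fit in this comparison were false, and 7.26% with the 6 arrays alone. The fit of the 6 arrays recovered 25% of the genes changed by a log2 of 1 and 90% of those changed by 2. Its 0 calls on the real arrays could therefore miss many changes of a log2 of 1.

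**Figure D3:**
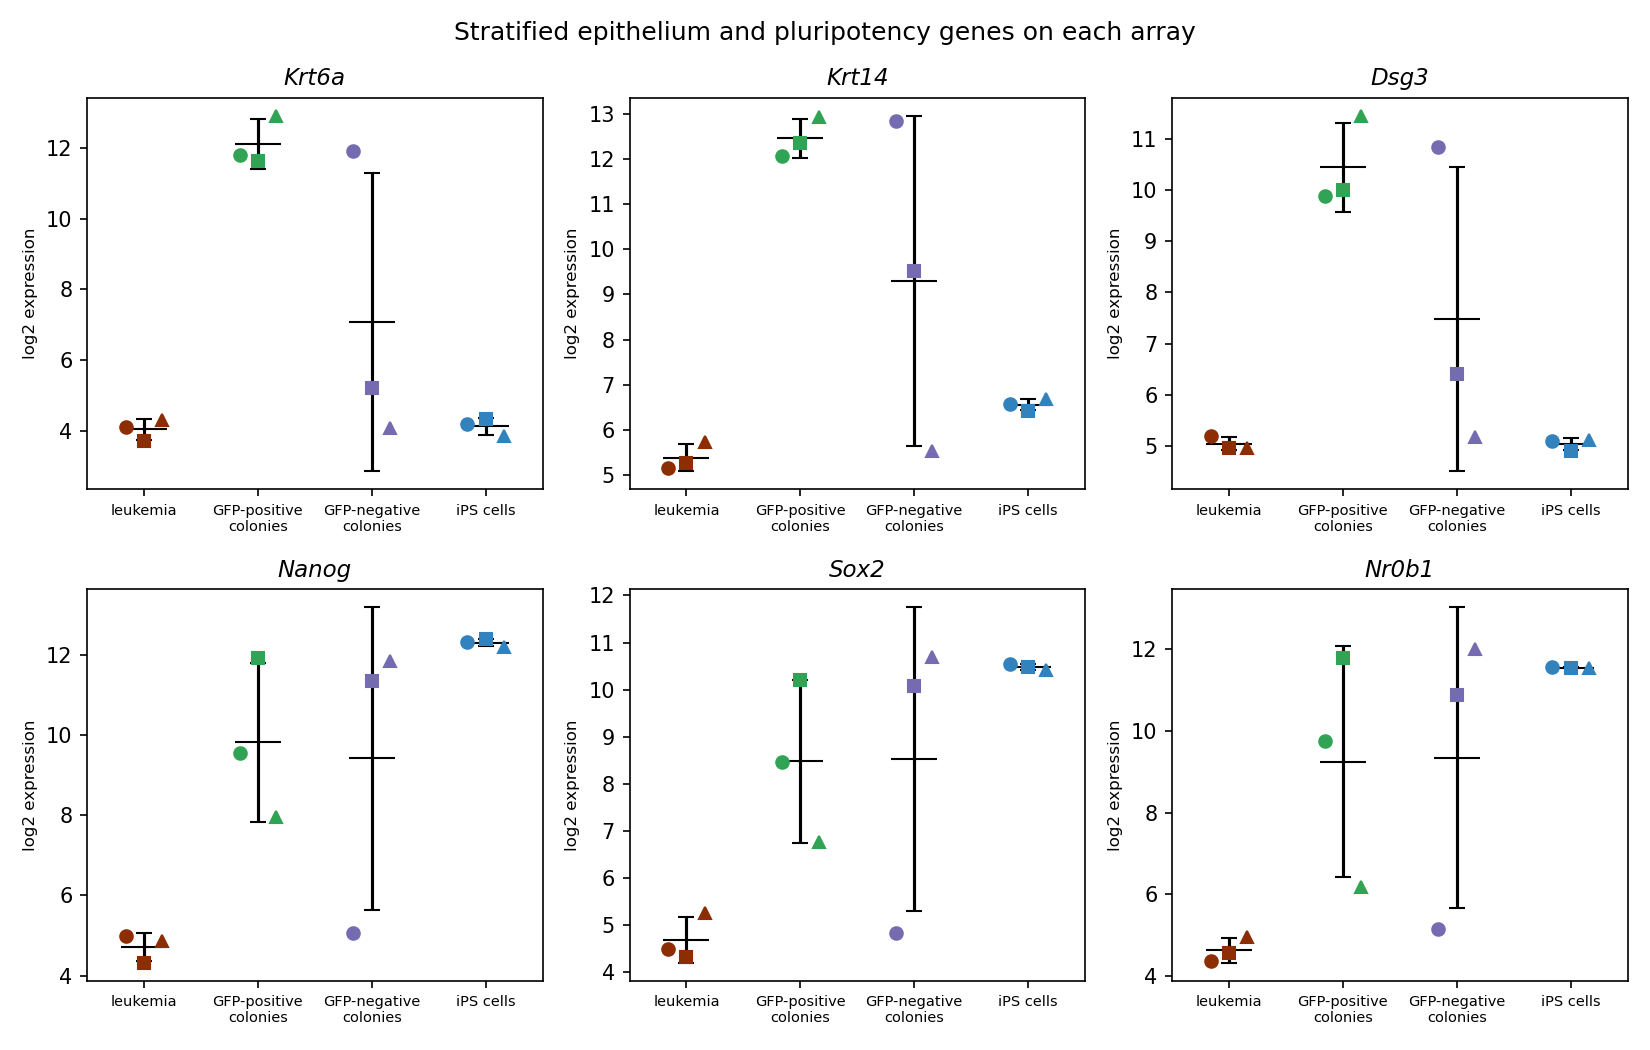
Log2 level of keratin and pluripotency genes on each array, by group. On GFP-negative replicate 1 Krt6a is at 11.91 and Nanog at 5.07, while replicates 2 and 3 have Krt6a at 5.22 and 4.09 and Nanog at 11.35 and 11.85.

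Established iPS cells had higher expression of matrix and fibroblast genes than GFP-negative colonies. Of 23 fibroblast and mesenchymal genes 16 rose and 7 were not called (19 adjusted over the list alone), with a median of 1.32 (camera adjusted p = 7.1e-17, and adjusted p = 0.0918 with an estimated correlation). The matrix proteoglycan gene Dcn rose from 5.61 ± 0.66 to 10.73 ± 0.08 (34.7-fold, adjusted p = 0.00105, limma), Fbln2 by 2.62 ± 0.56 and the collagen gene Col1a1 by 1.59 ± 0.32. The fibroblast genes that rose numbered 9, 8 and 9 without iPS replicates 1, 2 and 3. The Y-linked gene Eif2s3y, named after its values were seen, was at 7.01 to 7.69 on the iPS arrays and at 8.56, 3.84 and 3.21 on the GFP-negative arrays. The other largest increases were those of the matrix protease gene Mmp3 (5.47 ± 0.81, adjusted p = 0.00673), the tenascin gene Tnc (4.95 ± 0.58), the trypsin inhibitor gene Spink1 (4.13 ± 0.44) and Zscan4e (5.06 ± 0.47), of a family known from 2-cell embryos and a minority of embryonic stem cells. The 5 largest decreases were Oasl2 (-3.59 ± 0.54, adjusted p = 0.00711), Igtp (-3.50 ± 0.62), Rtp4 (-2.98 ± 0.61), Irgm2 (-2.93 ± 0.59) and Gbp7 (-2.87 ± 0.67), each known as interferon-inducible. In a list of 18 other interferon-stimulated genes, written after these were seen and before its own values were, 0 were called lower (limma, 4 adjusted over the list alone, camera p = 1.9e-05, and p = 0.247 with an estimated correlation). Of the 5 calls, all but that of Oasl2 were lost without any 1 iPS array.

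Pluripotency genes had a median difference of 1.15, with 1 of 28 called (2 adjusted over the list alone, camera adjusted p = 2.37e-04, and adjusted p = 0.73 with an estimated correlation). That gene was Tfcp2l1 (1.31 ± 0.28, adjusted p = 0.0302). The list averaged 6.61, 9.35 and 9.78 on GFP-negative replicates 1, 2 and 3, and without replicate 1 the median difference was 0.12, and 0.60 for the cassette's factors. Of the cassette's factors 2 rose (2 adjusted over the list alone), Klf4 by 1.45 ± 0.31 and Pou5f1 by 0.81 ± 0.17 (camera adjusted p = 0.0064, and adjusted p = 0.156 with an estimated correlation). Sox2 (1.96 ± 1.32), Myc (0.39 ± 0.29) and Nanog (2.88 ± 1.53, adjusted p = 0.329) were not called, and Nanog had an SD of 3.78 in GFP-negative colonies against 0.09 in iPS cells. Of 15 germline genes 3 rose (5 adjusted over the list alone), among them the meiotic gene Syce1 (1.77) and the germ cell helicase gene Ddx4 (0.80). Of 19 imprinted genes 3 rose (4 rose and 1 fell adjusted over the list alone), including Grb10 (2.31) and Plagl1 (1.05). Without GFP-negative replicate 1, 1 germline and 1 imprinted gene rose. Without iPS replicate 3, 1 germline gene rose. Of the imprinted genes 1 rose without GFP-negative replicate 2 and 0 without any 1 iPS array.

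The remaining lists had few calls. Dnmt3a, a DNA methyltransferase gene, was the 1 regulator of methylation and Polycomb that fell (-1.35), Themis the 1 T lineage gene (-0.51) and Car2 the 1 erythroid gene (-2.39), each with 1 adjusted over the list alone. The hexokinase gene Hk2 was the 1 glycolysis gene that rose (0.64, 1 higher and 1 lower adjusted over the list alone). Among the housekeeping genes Snrpd3 rose by 1.04 and Chmp2a fell (-1.30), with 2 higher and 2 lower adjusted over the list alone. Cd3e (-0.70 ± 0.82), Ptprc (-1.28 ± 0.73), Notch1 (-0.05 ± 0.09) and Epcam (-0.34 ± 0.19) were not called. Cell division genes had 0 called and a median of 0.54 (camera adjusted p = 4.69e-04, and adjusted p = 0.73 with an estimated correlation), and antigen presentation genes 0 called (1 fell adjusted over the list alone) and a median of -1.11 (camera adjusted p = 5.64e-04, and adjusted p = 0.73 with an estimated correlation). Without GFP-negative replicate 1 these medians were 0.19 and -0.68. Epithelial genes were placed lower with 0 called (median -0.68, camera adjusted p = 0.00127, and adjusted p = 0.73 with an estimated correlation). So were pan-haematopoietic genes, with 0 called (median -0.54, camera adjusted p = 0.00462, and adjusted p = 0.73 with an estimated correlation). The epithelial list averaged 10.03, 9.16 and 7.89 on GFP-negative replicates 1, 2 and 3 and 8.17 to 8.22 on the iPS arrays. Of the 20 lists, camera called 8 at the preset correlation and 0 with an estimated one.

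Limma called 651 genes higher and 292 lower in iPS cells than in GFP-negative colonies, which are 69.0% higher among the calls, against 33.2% after centring on the housekeeping genes and 56.7% with array weights. That centring moved the median of all genes by -0.27 and gave 4 fibroblast calls in place of 16, and the fit of the 6 arrays alone gave 7. The latter called 144 genes higher and 46 lower in all. In simulated data with the measured spread, 28.6% of the 4-group calls in this comparison were false, and 21.3% with the 6 arrays alone. Without iPS replicate 1, 2 or 3 the counts were 195, 196 and 178 higher and 83, 77 and 73 lower, and without GFP-negative replicate 3 they were 1023 and 732. Of 25 calls of named genes 7 were kept whichever array was left out (Mmp3, Dcn, Zscan4e, Tnc, Spink1, Oasl2 and Syce1). The other 18 were lost without iPS replicate 1 or 3, and 17 of them, all but Ddx4, without iPS replicate 2, with highest adjusted p values from 0.0673 for Igtp to 0.164 for Dnmt3a.

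Set against the leukemia, iPS cells had higher pluripotency and germline expression and lower T cell and other blood expression. Of 28 pluripotency genes 21 rose (25 adjusted over the list alone), with a median of 3.66 (camera adjusted p = 2.0e-12, and adjusted p = 0.188 with an estimated correlation). Nanog rose from 4.72 ± 0.35 to 12.31 ± 0.09 (192-fold, adjusted p = 0.00445, limma), Tdgf1 by 7.19 ± 0.53 and Sox2 by 5.80 ± 1.32. All 27 T lineage genes fell (27 adjusted over the list alone), with a median of -4.47 (camera adjusted p = 7.37e-35, and adjusted p = 0.0114 with an estimated correlation), among them Cd3g (-7.31 ± 0.52), Cd3d (-6.32 ± 0.37) and Cd3e (-5.23 ± 0.82). Ptprc differed by -6.32 ± 0.73 and Slamf6 by -6.78 ± 0.17, and Prss2 by -6.40 ± 0.17.

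The other largest increases were those of the zinc finger gene Zfp640 (8.13 ± 1.67, adjusted p = 0.00491), Nid1 (7.36 ± 0.58) and the X-linked gene Bex1 (7.26 ± 0.57). Of the cassette's factors 3 rose and 1 fell (3 and 1 adjusted over the list alone): Sox2, Pou5f1 (1.57), Klf4 (1.07, adjusted p = 0.0269) and Myc (-1.26). Of 16 Notch genes 9 fell and 1 rose (11 and 2 adjusted over the list alone, camera adjusted p = 6.78e-05, and adjusted p = 0.0179 with an estimated correlation), Notch1 at -2.71 and Ptcra at -2.66. Of 25 pan-haematopoietic genes 24 fell (24 adjusted over the list alone, camera adjusted p = 1.15e-19, and adjusted p = 0.0758 with an estimated correlation), including Ikzf1 (-6.09). Of 20 macrophage and granulocyte genes 9 fell and 1 rose (12 and 1 adjusted over the list alone, camera adjusted p = 4.44e-07, and adjusted p = 0.169 with an estimated correlation), Ngp at -5.96 and Camp at -5.53.

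Of 10 B cell genes 5 fell and 1 rose (6 and 1 adjusted over the list alone, camera adjusted p = 0.00177, and adjusted p = 0.0441 with an estimated correlation), Ighm at -4.08 and Ebf1, a B lineage factor also found in mesenchymal cells, at 1.28. Of 9 erythroid genes 7 fell (7 adjusted over the list alone, camera adjusted p = 2.61e-06, and adjusted p = 0.0179 with an estimated correlation), Car1 at -3.03 and the band 3 gene Slc4a1 at -2.16. Of 13 antigen presentation genes 9 fell (11 adjusted over the list alone), with a median of -2.51 (camera adjusted p = 9.36e-06, and adjusted p = 0.188 with an estimated correlation), the immunoproteasome gene Psmb8 at -4.11 and the class II gene H2-Ab1 at -4.08.

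Of 20 epithelial genes 12 rose (12 adjusted over the list alone, camera adjusted p = 1.13e-08, and adjusted p = 0.169 with an estimated correlation), Cdh1 by 5.42 and Epcam by 4.14. Of 23 fibroblast genes 18 rose (21 adjusted over the list alone, camera adjusted p = 1.35e-12, and adjusted p = 0.0441 with an estimated correlation), Fn1 by 6.06, Dcn by 5.96 and Col1a1 by 1.88. Of 15 germline genes 9 rose (11 adjusted over the list alone, camera adjusted p = 3.05e-05, and adjusted p = 0.169 with an estimated correlation), including Dazl, an RNA-binding protein of germ cells (4.26), and Tex19.1 (3.42). Of 19 imprinted genes 8 rose (10 adjusted over the list alone, camera adjusted p = 2.24e-04, and adjusted p = 0.169 with an estimated correlation), Mest by 4.54 and Grb10 by 4.39. Of 20 methylation and Polycomb regulators 7 rose and 5 fell (8 and 6 adjusted over the list alone), the dioxygenase genes Tet1 and Tet2 by 3.86 and 3.18. The list's median was -0.09 and its mean 0.64, of opposite sign. Of these regulators 4 rose without iPS replicate 1 or 3 or leukemia replicate 2 or 3.

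Smaller groups of calls were found in the other lists. Of 23 early germ-layer genes 5 rose (5 adjusted over the list alone, camera adjusted p = 0.0358, and adjusted p = 0.169 with an estimated correlation), Bmp4 by 3.06 and Otx2 by 2.57. With 1 array left out in turn, 1 to 3 of the early germ-layer genes rose, with 1 without iPS replicate 1 or leukemia replicate 3. In the cell division list Mki67 was among 2 that fell (-1.15) and Cdc20 the 1 that rose (1.11, 2 and 1 adjusted over the list alone). In the inhibitor and p53 list 4 rose and 3 fell (4 and 3 adjusted over the list alone), Cdkn1a by 3.16 and Sesn2 by 2.40. Of 14 glycolysis genes 5 rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.0161, and adjusted p = 0.188 with an estimated correlation), Slc2a3 by 2.92 and Slc2a1 by 2.54. Xist was the 1 sex-chromosome gene called (-3.89 ± 0.92, 1 adjusted over the list alone). Of the housekeeping genes 3 rose and 1 fell (5 and 2 adjusted over the list alone), the proteasome gene Psmb4 at 0.63 and Chmp2a at -0.81.

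Between iPS cells and leukemia 2759 genes were higher and 2636 lower (limma). The share of higher genes was 51.1%, and 25.6% after centring on the housekeeping genes, which moved the median of all genes by -0.36. Of 48 calls of named genes 41 were kept whichever array was left out. The calls of Ebf1, Tet1, Otx2, H2-Ab1, Chmp2a and Klf4 were lost without any 1 of the 6 arrays, and that of Cdc20 without any 1 but leukemia replicate 3, with highest adjusted p values from 0.0586 for Cdc20 to 0.110 for H2-Ab1. The spread in this fit is estimated over all 4 groups, the colonies included, and each array left out lowers its precision. The fit of the 6 arrays alone called 5438 genes higher and 5087 lower. The counts fell alike whichever array was left out, to 1978 to 2035 higher and 1922 to 1984 lower. This argues against a single array as the source of the losses. How much of them comes from the shared estimate was not tested.

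GFP-negative colonies, like GFP-positive ones, had lower T cell and higher epithelial expression than the leukemia. All 27 T lineage genes fell (27 adjusted over the list alone, median -4.47, camera adjusted p = 3.59e-36, and adjusted p = 0.0101 with an estimated correlation), 24 of 25 pan-haematopoietic genes fell (25 adjusted over the list alone, camera adjusted p = 2.31e-18, and adjusted p = 0.106 with an estimated correlation), and 17 of 20 epithelial genes rose (18 adjusted over the list alone, camera adjusted p = 7.64e-14, and adjusted p = 0.143 with an estimated correlation). Of 28 pluripotency genes 8 rose (15 adjusted over the list alone, camera adjusted p = 3.4e-08, and adjusted p = 0.329 with an estimated correlation). Camera called 15 of the 20 lists at the preset correlation and 3 with an estimated one. Limma called 2001 genes higher and 2654 lower, 43.0% higher among the calls and 53.4% after cyclic loess. Epcam (4.48 ± 0.19) and Pou5f1 (0.77 ± 0.17) rose, and Ptprc (-5.04 ± 0.73), Cd3e (-4.53 ± 0.82), Notch1 (-2.66 ± 0.09) and Myc (-1.65 ± 0.29) fell, calls that were kept whichever array was left out. Nanog (4.70 ± 1.53, adjusted p = 0.053), Sox2 (3.84 ± 1.32, adjusted p = 0.0645), Klf4 (-0.38) and Col1a1 (0.29) were not called.

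From GFP-positive colonies to iPS cells, 14 of 23 fibroblast genes rose (17 adjusted over the list alone, camera adjusted p = 3.67e-09, and adjusted p = 0.255 with an estimated correlation). In the other direction 8 of 13 antigen presentation genes fell (10 adjusted over the list alone, median -2.27, camera adjusted p = 3.75e-08, and adjusted p = 0.417 with an estimated correlation), as did 9 of 25 pan-haematopoietic genes (13 adjusted over the list alone, camera adjusted p = 1.55e-07, and adjusted p = 0.417 with an estimated correlation) and 7 of 20 epithelial genes (14 adjusted over the list alone, camera adjusted p = 1.15e-06, and adjusted p = 0.417 with an estimated correlation). Without GFP-positive replicate 3 the median of the antigen presentation genes was -1.40. Camera called 10 of the 20 lists at the preset correlation and 0 with an estimated one. Among them pluripotency genes were higher (median 1.33, 1 of 28 called, camera adjusted p = 8.86e-05, and adjusted p = 0.552 with an estimated correlation). So were germline genes (3 of 15 called, camera adjusted p = 6.46e-04, and adjusted p = 0.417 with an estimated correlation) and cell division genes (2 of 15 called, camera adjusted p = 1.43e-04, and adjusted p = 0.552 with an estimated correlation). The T lineage, Notch and macrophage lists were lower. Pou5f1 (0.89 ± 0.17) and Col1a1 (1.18 ± 0.32, adjusted p = 0.0416) rose, and Ptprc (-3.91 ± 0.73) and Notch1 (-0.33 ± 0.09, adjusted p = 0.0493) fell. Differences were 2.01 ± 1.32 for Sox2, 2.49 ± 1.53 for Nanog, 0.50 ± 0.31 for Klf4, 0.07 ± 0.29 for Myc, -2.14 ± 0.82 for Cd3e and -0.33 ± 0.19 for Epcam, none of them called.

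Limma called 1365 genes higher and 939 lower in iPS cells than in GFP-positive colonies, with 59.2% higher among the calls, against 48.3% after cyclic loess and 26.5% after housekeeping centring (shift of the median of all genes -0.36). The counts were 405, 418 and 409 higher and 194, 206 and 188 lower without iPS replicates 1, 2 and 3, and 560 and 340 without GFP-positive replicate 1. They were 768 and 421 without GFP-positive replicate 3, and 1427 lower without GFP-positive replicate 2. Each of the 4 named calls was lost without at least 1 array, Pou5f1 without iPS replicate 3 (adjusted p = 0.0514), Ptprc without iPS replicate 1 or 3 (highest adjusted p = 0.0512), and Notch1 and Col1a1 without any 1 of 5 arrays (highest adjusted p = 0.149 and 0.143).

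The position of the colonies between leukemia and iPS cells was measured over 2756 genes. GFP-positive colonies lay at 0.726 ± 0.130, with arrays at 0.756, 0.838 and 0.583, and GFP-negative colonies at 0.799 ± 0.120, with arrays at 0.664, 0.839 and 0.893 (mean ± SD, n = 3). The difference of 0.0734 was within the spread between arrays (two-sided exact permutation p = 0.5, n = 3 per group, where 0.1 is the smallest p the design allows). It was 0.149 without GFP-negative replicate 1 and 0.000428 without GFP-positive replicate 3. On the pluripotency list alone the GFP-positive arrays lay at 0.618, 0.949 and 0.303 and the GFP-negative arrays at 0.156, 0.894 and 1.01.

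**Figure D4:**
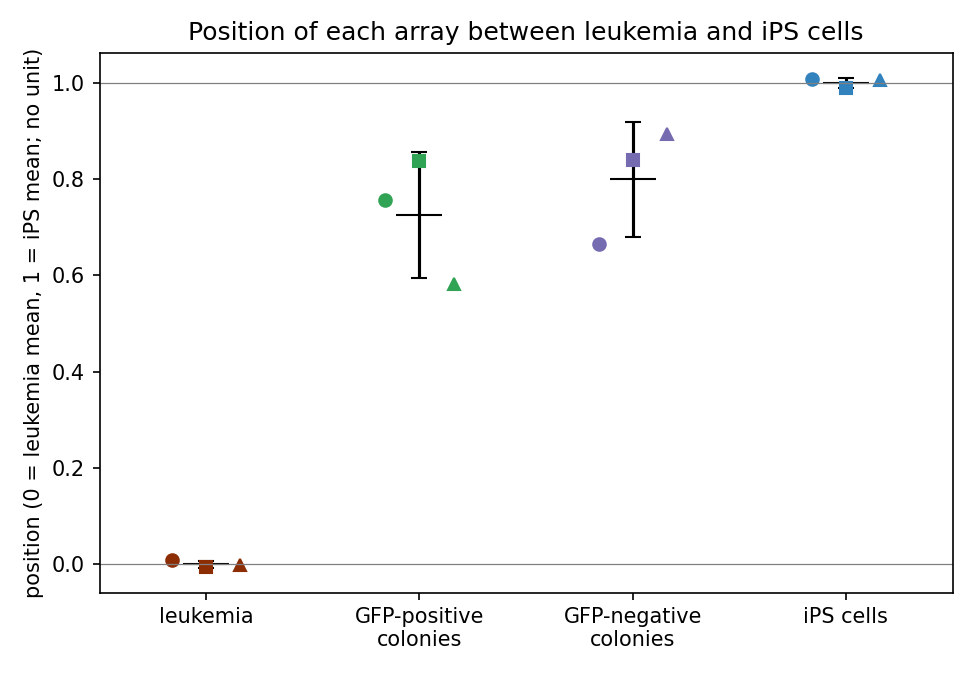
Position of each array on the axis from the leukemia mean (0) to the iPS mean (1) over 2756 genes, by group. The GFP-positive arrays lie from 0.583 to 0.838 and the GFP-negative arrays from 0.664 to 0.893, so the groups overlap.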

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

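The block for the Y-linked genes, the spread differing between groups and leaving out both GFP-positive replicate 3 and GFP-negative replicate 1 (both doubted arrays) were chosen after seeing the data, and the other alternatives before. Directions held for every call of a named gene: of 130 calls, 130 were kept with the mean of all probe sets, 129 with array weights, 128 without both doubted arrays, 127 with an intensity trend and robust prior, 126 with a differing spread, 125 with cyclic loess, 109 with housekeeping centring, 106 with the 6 arrays of the groups compared, and 97 with the Y block. Of the 124 with a value above the 40th percentile, 124 were kept. No call reversed. Counts of called genes under the trend, mean probe set, 40th percentile and cyclic loess settings stayed within 1.5 times the reported ones. Over the 6 comparisons camera called 68 of 120 list results at the preset correlation, of which 10 were also called with an estimated correlation and 58 were lost, and the other 52 were called with neither. Background signal was not measured, so the level under which a probe set carries no signal is unknown, and the 3 arrays per group limit what can be called. Except where fewer arrays or genes enter a setting, the cause was not tested.

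The replicate numbers did not pair the arrays: same-numbered arrays of the colony groups deviated from their group means with correlations of 0.168, 0.322 and -0.377 across genes, and those of the other comparisons with -0.06 to 0.06. With the replicate block the counts higher and lower were 2071 and 2535 (GFP-positive colonies against leukemia), 0 and 0 (GFP-negative against GFP-positive colonies), 510 and 229 (iPS cells against GFP-negative colonies), 2610 and 2494 (iPS cells against leukemia), 1924 and 2472 (GFP-negative colonies against leukemia) and 1141 and 774 (iPS cells against GFP-positive colonies), and 120 of the 130 named calls were kept. The camera result of early germ-layer genes between iPS cells and GFP-negative colonies, not called, turned its direction with the replicate block (adjusted p = 0.947).

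In the same order of comparisons, array weights called 3859 higher and 4329 lower, 405 and 910, 2492 and 1905, 5267 and 5278, 4230 and 4443, and 3910 and 3074. Without both doubted arrays there were 3486 higher in GFP-positive colonies than in leukemia, 273 higher and 776 lower between the colony groups, 1298 and 924 between iPS cells and GFP-negative colonies, 4195 higher in iPS cells and 3573 higher in GFP-negative colonies than in leukemia, and 2475 and 2060 between iPS cells and GFP-positive colonies. With at least 2-fold change the counts were 1394 and 991, 0 and 0, 220 and 107, 1517 and 1239, 1156 and 1074, and 399 and 547. The 6 arrays alone gave 144 and 46 for iPS cells against GFP-negative colonies and 5438 and 5087 for iPS cells against leukemia. Housekeeping centring gave 96 and 193 for iPS cells against GFP-negative colonies, 1408 and 4082 for iPS cells against leukemia, and 221 and 614 for iPS cells against GFP-positive colonies. Among all probe sets, which are more features, 4318, 4173 and 4366 were lower against leukemia in GFP-positive colonies, iPS cells and GFP-negative colonies. The higher ones rose less, to 2502 in GFP-positive colonies and 3403 in iPS cells, and the cause was not tested. The Y block gave 1 lower gene between the colony groups (Klk1, -4.89, named after its value was seen), 488 lower in iPS cells than in GFP-negative colonies, and 1625 and 1724 between iPS cells and leukemia. A differing spread gave 5180 and 5248 for iPS cells against leukemia and 2351 and 1942 for iPS cells against GFP-positive colonies.

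Leaving out 1 array in turn gave 1492 to 2124 higher and 1907 to 2648 lower for GFP-positive colonies against leukemia, 0 to 251 and 0 to 768 between the colony groups, 178 to 1023 and 73 to 732 for iPS cells against GFP-negative colonies, 1978 to 2035 and 1922 to 1984 for iPS cells against leukemia, 1368 to 2883 and 1894 to 3150 for GFP-negative colonies against leukemia, and 405 to 1995 and 188 to 1427 for iPS cells against GFP-positive colonies. The position difference ran from 0.000428 to 0.149, and was 0.0761 over all genes and 0.0909 after housekeeping centring.

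Differences that changed sign were all uncalled in the reported fit. Between the colony groups, Sox2 was -0.032 with housekeeping centring, -0.44 with the Y block and -1.03 to 1.91 with 1 array left out; Nanog was 1.27 with array weights, 0.85 without both doubted arrays and -1.61 to 1.78 with 1 array left out. Epcam was -0.019 with array weights, -0.018 with cyclic loess, -0.075 with housekeeping centring, -0.11 without both doubted arrays and -0.22 to 0.20 with 1 array left out. Myc was 0.025 with array weights and -0.53 to 0.0015 with 1 array left out, and Pou5f1 ran from -0.057 to 0.25. Between iPS cells and GFP-negative colonies, Notch1 was 0.013 with the Y block, and Cd3e 0.31 with array weights, 0.55 without both doubted arrays (where it was called) and -1.34 to 0.55 with 1 array left out. Col1a1 was -0.040 in GFP-negative colonies against leukemia with array weights. Myc in iPS cells against GFP-positive colonies was -0.059 with cyclic loess, -0.29 with housekeeping centring and -0.14 to 0.37 with 1 array left out. Of 160 counts of called list members, 94 stayed within 1.5 times with array weights, 112 without both doubted arrays, 127 with the Y block, 132 with the 6 arrays alone, 138 with housekeeping centring and 152 with the replicate block.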

Other observations

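The tests on GFP-negative replicate 1, the Y-linked genes, array scaling and the splits of the arrays were chosen after their results had been seen, and those on the second fibroblast list and the interferon list before. Genes below that the rule did not name were chosen after their values were seen.

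Macrophage and class II genes were high on single colony arrays. C1qb, a complement gene of macrophages, measured 10.87 on GFP-positive replicate 3 and 9.11 on GFP-negative replicate 2, Tyrobp, a myeloid adaptor gene, 10.28 and 7.47, and the class II gene H2-Ab1 12.58 and 9.96, against 10.17 ± 0.02 for H2-Ab1 in leukemia. The macrophage and granulocyte list averaged 6.78 ± 1.21 in GFP-positive colonies, with the highest array at 8.18, and 5.85 ± 0.09 in iPS cells. The epidermal adhesion gene Dsg3 followed the keratins, at 9.88 to 11.44 on the GFP-positive arrays and 10.83, 6.41 and 5.19 on the GFP-negative arrays.

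The 5 largest decreases from GFP-negative colonies to iPS cells are interferon-inducible genes, which led to the hypothesis that such genes are lower as a group. In a list of other interferon-stimulated genes, limma called 0 of 18 lower (4 adjusted over the list alone), so the hypothesis was not borne out by calls, although the median was -1.25 (camera p = 1.9e-05, and p = 0.247 with an estimated correlation). Called or not, 15 of the 18 were lower in iPS cells, so the 0 calls do not exclude a decrease of the group. The list averaged 8.34, 6.47 and 6.75 on GFP-negative replicates 1, 2 and 3 and 5.99 to 6.04 on the iPS arrays. Between iPS cells and GFP-positive colonies 11 of the 18 fell.

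GFP-negative replicate 1 lay apart from the other GFP-negative arrays, with keratins high and pluripotency genes low. Cells of another animal, as read from the Y-linked genes, stay open: colony arrays of the same Y status correlated at 0.945 ± 0.0383 and arrays of different status at 0.945 ± 0.0281 (mean ± SD over 6 and 9 pairs), a difference of 0.000192 that decides nothing, and replicate 1 itself correlated at 0.976 and 0.950 with the Y-positive colony arrays and at 0.962, 0.933 and 0.887 with the others. Exchanged labels with GFP-positive replicate 2 also stay open: that array correlated better with GFP-negative replicates 2 and 3 (mean r 0.973) than with the other GFP-positive arrays (0.956, difference 0.017). Krt6a goes the other way, at 11.63 on GFP-positive replicate 2 and at 5.22 and 4.09 on GFP-negative replicates 2 and 3. A single wrong label, or colonies at different stages of reprogramming within a group, may also account for it and were not tested.

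The Y-linked genes Eif2s3y and Uty were above 5.5 on GFP-positive replicates 1 and 2, GFP-negative replicate 1 and all iPS arrays, and below it on the leukemia arrays. For the 3 colony arrays, fibroblast feeder cells stay open: the fibroblast list averaged 6.48 ± 0.248 on them and 6.38 ± 0.426 on the other 3, and the difference of 0.101, within their spread, speaks neither for nor against them. Colonies and leukemia from animals of different sex stay open as well. Xist on these 3 arrays lay at least 3.61 below the lowest leukemia array. On GFP-positive replicate 3, without the Y-linked signal, Xist was the highest of the colony arrays and just below the leukemia arrays, which goes with different sex. The other colony arrays without that signal go the other way. Xist was lowest, at 6.39, on GFP-negative replicate 3 and at 9.48 on GFP-negative replicate 2, so low Xist alone does not mark sex here. In the iPS arrays, feeder cells and the cells' own origin cannot be told apart, since all 3 carry both signals and their fibroblast list lay at least 0.793 above every colony array. Kdm5d, a further Y-linked gene, was at 4.16 to 4.46 on the iPS arrays, near the 3.99 to 4.27 of leukemia, whereas Eif2s3y was at 7.01 to 7.69 on the iPS arrays. On GFP-positive replicates 1 and 2 and GFP-negative replicate 1, Kdm5d was at 6.76, 6.17 and 6.95 and Eif2s3y at 8.53, 7.49 and 8.56. The fibroblast list averaged 6.20 to 6.68 on these colony arrays and 7.65 to 7.73 on the iPS arrays. Whether the Y-linked signals of the colony and iPS arrays have the same source was not tested.

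Fibroblast genes were higher in iPS cells than in GFP-negative colonies. Array scaling as the whole cause is argued against only if the housekeeping genes give the true scale. Centring on them moved every gene by -0.27, and so the list's median difference from 1.32 (quartiles 0.75 to 1.94) to 1.05 (quartiles 0.48 to 1.67). An equal shift of every gene cannot change the list's distance from all genes. The housekeeping genes themselves differed by -1.30 to 1.04 in this comparison. A part of the difference stays open to array scaling, namely that by which the list's median fell under this centring. The calls went from 16 to 4 as the median standard error of the list rose from 0.25 to 0.34 and the differences shrank. Over all genes that error rose from 0.17 to 0.24, so the loss of calls is no evidence for scaling. Feeder fibroblasts in the iPS cultures, a candidate explanation since iPS cells are often grown on feeders, stay open: in a second list of fibroblast genes 11 of 18 rose and 0 fell (13 adjusted over the list alone, median 1.48, camera p = 8.6e-14, and p = 0.0195 with an estimated correlation), the matrix gene Bgn by 3.82, Cdh11 by 2.83 and Aebp1 by 1.82. A change in the cells themselves was not tested apart from this, and leukemia arrays had 6 of the 18 genes above the array median, GFP-positive colonies 11, GFP-negative colonies 9 and iPS cells 13.

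Other splits of the 6 arrays of each comparison were also fitted, 10 per comparison with the real one, which are too few for a share under 0.05. The real split called 4848 genes for GFP-positive colonies against leukemia, 943 for iPS cells against GFP-negative colonies, 5395 for iPS cells against leukemia, 4655 for GFP-negative colonies against leukemia and 2304 for iPS cells against GFP-positive colonies, and in each of these the highest other split called 0, so that 1 of the 10 splits called as many as the real one. In these comparisons every other split mixes arrays of both groups, which puts the difference between the groups into the spread. Such splits could hardly call genes, so their 0 calls decide nothing. Between the colony groups the real split called 0 genes, which all 10 splits reach whatever they call, so their number says nothing. The highest of the other 9 called 5845. It is the same fit as the exchange of GFP-negative replicate 1 with GFP-positive replicate 2, and regrouping arrays by their similarity raises the calls by itself, so it is no further evidence for that exchange. As a split that calls many genes where the real one calls 0, it leaves open some structure other than the GFP groups as labelled. It decides nothing, being the highest of 9 splits. In simulated data with the measured spread, 54.0% of the calls of the 4-group fit between the colony groups were false.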
